A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

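Cultures of the yeast strain BY4741 were grown to early exponential phase in rich medium at 30 °C and 250 rpm, then left untreated or given 0.05 mM acrolein, 0.3 mM H2O2 or 0.016 mM NEM for 1 h, per the labels. Labelled RNA (8 µg) was hybridised to Affymetrix Yeast Genome 2.0 arrays, 4 per group and 16 in all. The authors normalised the arrays with GCRMA, a background correction and summary of probe signals, and the values were deposited as log2 signal. The GCRMA version is not given in the sources used here. The deposited log2 values were used as they stand, with no further scaling. Array medians over the tested probe sets ran from 11.85 to 11.92.

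The array carries 10928 probe sets, and 166 control probe sets and 1747 annotated to another yeast species were left out. The names of the remaining ones came from the platform annotation and the reference gene table (assembly R64), with 12 symbols updated. Of 5498 named probe sets 49 were dropped for a brighter one of the same gene, by the mean over all arrays, which left 5449 genes, and 45 of these were constant on all arrays. Another 3517 probe sets had no gene name, and 3136 of them were constant. Constant probe sets cannot be tested and were left out, a departure from the plan, which set no such filter. The 5785 tested probe sets comprise 5404 genes and 381 without a name, which were tested but are not named. Of the 1747 other-species probe sets 1663 were constant, so most of the unnamed ones resembled them in this. The species of the 381 was not checked, so some may belong to the other yeast, and totals over 5785 include them.

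All 16 arrays entered 1 linear model with a mean per group in limma 3.58.1 (R 4.3.3), with 12 residual degrees of freedom and empirical Bayes variances (prior degrees of freedom 1.15, prior SD 0.0729). Each treatment was compared with the control and with the other treatments, two-sided. Benjamini-Hochberg adjustment ran over the probe sets within a comparison, and adjusted p under 0.05 counted as called. Errors of differences are the standard errors of this model, and 95% intervals use its moderated variances. An F-test over the 3 treatment comparisons gave the number changed by any treatment. RNA-quality measures were compared by exact permutation tests, and by exact sign-flip tests where replicate numbers pair the arrays, the latter added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

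The comparisons, tests, 45 gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. The rule names, per treatment, the 10 largest increases and 10 largest decreases among called genes whose 4 treated arrays all lie beyond the 4 control arrays. It names the 5 largest in each direction between treatments, up to 4 called members with the largest change per described list, and up to 5 treatment-specific genes per direction. It always names 13 chosen response genes, the genes deleted from the strain and ACT1. The text gives a selection of these. A gene is specific to a treatment when it was called against the control and against both other treatments in 1 direction. Of the lists, 43 had at least 5 measured members and were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry stand beside it. The lists described were selected after their results were seen.

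Where all 4 arrays of a group lay at or under 5.15, the highest value of the other-species probe sets, the fold is given as a bound against that level. The bound uses the mean of the other group and makes no allowance for the error of that mean. This limit was chosen after seeing the data. Overlaps between treatments were set beside 100 simulations of unchanged groups that shared simulated control arrays. They were also set beside the product of the list sizes over the number tested, and beside fits with the controls split into pairs of arrays.

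Arrays with the same replicate number were checked for pairing by the correlation of their residuals. It was 0.20 to 0.51 between acrolein and control, 0.34 to 0.60 between NEM and control and 0.34 to 0.49 between acrolein and NEM, so these numbers pair the arrays. H2O2 replicates 3 and 4 correlated with their own number in every other group, but replicates 1 and 2 did not. A replicate block was therefore an alternative.

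Other settings fixed in advance were a replicate block, a fit of the 2 groups compared alone, a trended and robust prior, array weights, quantile normalization, median centring, filters on dim probe sets, a floor of 4, averaged probe sets, stricter thresholds, other list tests, other overlap measures and each array left out in turn. Added after seeing the data were named genes alone, the ribosomal RNA signal as a covariate, and a fit without acrolein replicate 1 and NEM replicate 4. The covariate was first run with 4 chosen probe sets and then with all 7.

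The fit was tested on simulated data with 50 changed genes per effect size among 5785. Effects of 0.5 on the log2 scale were recovered for 78% of genes in the acrolein run, 72% in the H2O2 run and 68% in the NEM run. The runs shared the same means and spreads and differed only in the arrays shifted and the random draws. Their shares therefore do not rank the treatments. Effects of 1 were recovered for 94%, 98% and 96%, and effects of 2 and 4 for 100%. False calls made up 5%, 5% and 5.88% of calls. A shifted list was recovered and 0 of 42 other lists were called. The simulated genes varied independently, so this does not test list calls where the members of a list move together. Raw probe intensities were not used here.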

Results

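Transcript levels were measured in the haploid budding yeast strain BY4741 on 16 Affymetrix Yeast Genome 2.0 arrays, each a set of short-oligonucleotide probe sets that report 1 transcript apiece. The arrays fall into 4 groups of 4: an untreated control, and cells given 0.05 mM acrolein, 0.3 mM H2O2 or 0.016 mM NEM for 1 h. Acrolein is the simplest alpha,beta-unsaturated aldehyde, H2O2 is hydrogen peroxide, and NEM is read here as N-ethylmaleimide, an alpha,beta-unsaturated imide, since the labels give only the abbreviation. The labels place all cells in early exponential phase in rich glucose medium at 30 °C. The comparisons ask which transcripts each treatment changed, and where the treatments differed from each other. The number of arrays, 4 per group, limits the precision, and the median standard error of a difference between group means was 0.086 on the log2 scale. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

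Of 5785 probe sets tested, 4614 (79.8%) changed in at least 1 treatment by limma's F-test. Acrolein changed 3704 probe sets, 1572 upward and 2132 downward, and 763 of these by at least 2-fold. NEM changed 3390, of which 1527 rose, 1863 fell and 650 moved at least 2-fold. H2O2 changed 1148, of which 534 rose, 614 fell and 141 moved at least 2-fold. The 4 treated arrays lay entirely above or below the 4 control arrays for 57.8% of probe sets after acrolein, 54.5% after NEM and 25.2% after H2O2, against 2.86% for chance. Doses differed between the compounds, so these counts rank neither their potency nor their specificity.

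**Figure D1:**
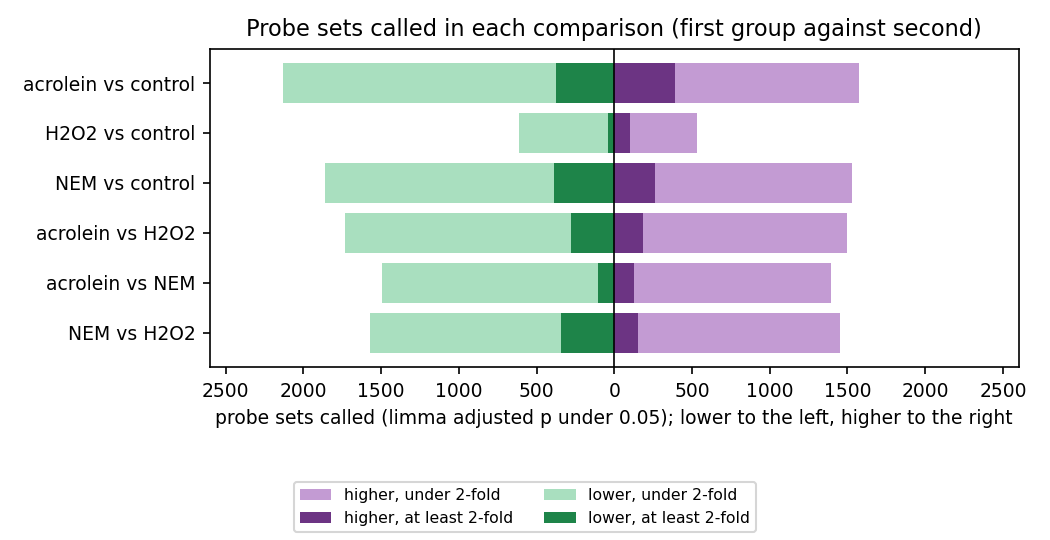
Number of probe sets called in each of the 6 comparisons (limma adjusted p under 0.05), with lower ones to the left of 0 and higher ones to the right, and the dark part of each bar for changes of at least 2-fold. H2O2 against the control has the shortest bars, with 534 higher and 614 lower.

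Marker genes deleted from the strain served as a check of the labels. URA3 and MET17 stood at the lowest value of the file on every array, and LEU2 on 15 of 16 arrays, with 1.98 on the remaining one. HIS3, a marker deleted only in part in this strain, read 11.06 to 12.27 over all arrays, so it gave no check of the labels. It stood at 11.23 ± 0.20 (SD, n = 4) in the control and changed by 0.78 ± 0.11 (SE) after acrolein (limma adjusted p = 4.42e-05). ACT1, the actin gene often used as a reference, differed from the control by 0.08 ± 0.05 after acrolein (adjusted p = 0.212) and by 0.02 ± 0.05 after H2O2 (adjusted p = 0.801). After NEM it was 0.15 ± 0.05 higher (adjusted p = 0.0188), a call that ended after quantile normalization (0.11, adjusted p = 0.0981), without control replicate 3 (0.13, adjusted p = 0.0585) and without NEM replicate 4 (0.13, adjusted p = 0.0591). Its H2O2 difference changed sign, to -0.01, without H2O2 replicate 4.

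Acrolein replicate 1 stood apart in RNA quality. Its 7 ribosomal RNA probe sets averaged 15.48 on the log2 scale, against 8.75 to 11.55 on the control arrays, and its 3′ minus 5′ signal over 7 transcripts averaged 1.20, against 0.60 to 0.78 on the other 15 arrays. H2O2 replicates 1 and 4 lay below the control range in ribosomal RNA signal, at 7.80 and 4.38. The 5.8S probe set of H2O2 replicate 4 read 4.53, against 12.25 to 15.45 on the other 15 arrays. The difference in ribosomal RNA signal from the control was 1.63 for acrolein, -2.01 for H2O2 and 0.93 for NEM (exact permutation p = 0.314, 0.343 and 0.4, two-sided, n = 4, smallest possible 0.0286). Single arrays weighed on these differences, which ran from 0.55 to 2.65, -2.99 to -0.60 and 0.31 to 1.70 with 1 array left out. The values nearest to 0 came without acrolein replicate 1, H2O2 replicate 4 and control replicate 4. For the 3′ minus 5′ signal the differences were 0.16, 0.09 and 0.03 (exact permutation p = 0.171, 0.0857 and 0.4), and with 1 array left out they ran from 0.03 to 0.22, 0.07 to 0.12 and 0.02 to 0.07. Paired by replicate number, ribosomal RNA signal was higher in all 4 pairs for acrolein and for NEM (exact sign-flip p = 0.125 for each, two-sided, the smallest possible with 4 pairs). The 3′ minus 5′ signal was higher in 4 of 4 pairs for acrolein (exact sign-flip p = 0.125) and in 3 of 4 for NEM (p = 0.375 by the same exact test). Replicate 1 carried the acrolein value, with a pair difference of 0.61, and the mean of the other 3 pairs was 0.02.

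**Figure D2:**
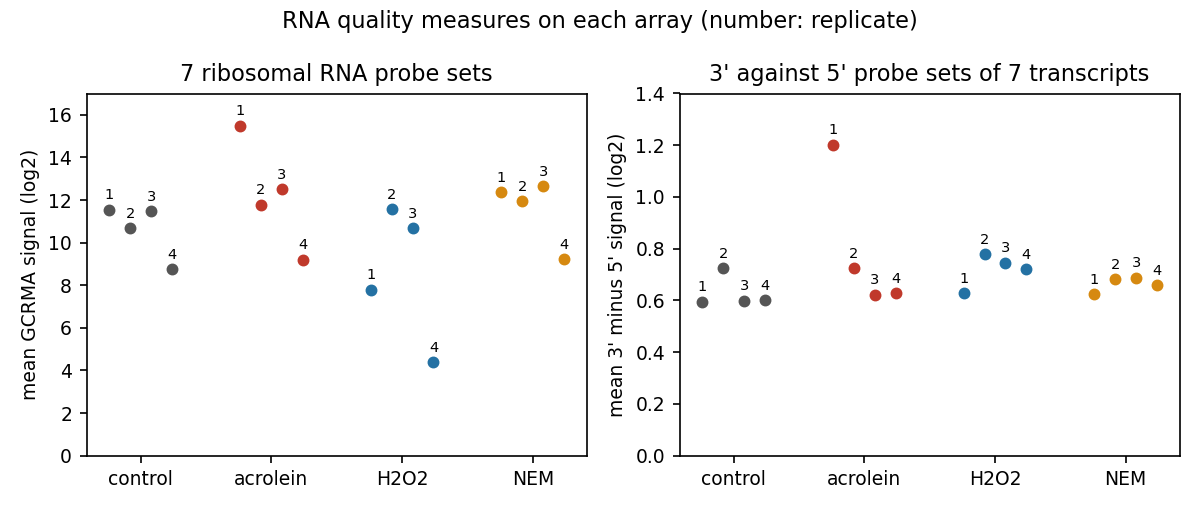
Mean log2 signal of 7 ribosomal RNA probe sets (left) and mean 3′ minus 5′ log2 signal of 7 transcripts (right), 1 point per array with its replicate number. Acrolein replicate 1 is the highest point in both, at 15.48 and 1.20.

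Acrolein raised several oxidoreductase and efflux genes. OYE3, an NADPH oxidoreductase of the old yellow enzyme family, rose by 8.68 ± 0.16 on the log2 scale (SE, n = 4 per group, limma adjusted p = 1.99e-13), from 6.79 ± 0.43 (SD) in the control. FRM2, a nitroreductase-like gene, was at least 94.2-fold higher and YHK8, a predicted drug transporter, at least 203-fold higher, both bounds because the control lay within the background range. ATR1, an efflux pump, rose by 5.17 ± 0.14, TAH18, a diflavin reductase, by 4.76 ± 0.15, and the open reading frames YLR460C and YCR102C by 8.20 ± 0.20 and 6.51 ± 0.12. YKL070W was called higher too, but its control mean of 4.28 lay under the background limit, so no value is given. Among the decreases, DAL80, a repressor of nitrogen catabolite genes, was at least 111-fold lower. The ammonium permease MEP2 fell by 5.01 ± 0.19, and the glucose-repressed alcohol dehydrogenase ADH2 fell by 5.37 ± 0.34. In the control MEP2 read 15.28 ± 0.02 and ADH2 13.98 ± 0.37 (SD), above every array median, so these falls start from a high control signal.

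Targets of Yap1, the transcription factor of oxidant defence, rose after acrolein, 14 of 19 measured members up and 1 down, the same adjusted over the list alone. Examples were GTT2, a glutathione transferase, at 3.58 ± 0.07 and FLR1, a drug transporter, at 2.99 ± 0.07. The list's median was 1.39 (camera adjusted p = 1.23e-08; adjusted p = 0.127 with an estimated correlation). GSH1, which starts glutathione synthesis, rose by 1.65 ± 0.08 and TRR1, thioredoxin reductase, by 0.96 ± 0.09, whereas YAP1 itself differed by 0.08 ± 0.16 (adjusted p = 0.683) and by -0.04 without acrolein replicate 4. In the glutathione and glutaredoxin list 14 of 24 rose and 8 fell, the same adjusted over the list alone, with GPX2 at 2.54 ± 0.11 and GTO3 at -4.05 ± 0.39 (camera adjusted p = 0.00645; adjusted p = 0.411 with an estimated correlation). Multidrug transporters gave 10 up and 6 down of 20, the same adjusted over the list alone, led by ATR1 and by AQR1 at 3.81 ± 0.21 (camera adjusted p = 0.0106; adjusted p = 0.219 with an estimated correlation). Of 5 aryl-alcohol dehydrogenases 3 rose and 2 fell, the same adjusted over the list alone, with AAD6 at 3.14 ± 0.19 and AAD14 at -0.67 ± 0.12. As a list they did not pass (camera adjusted p = 0.113; adjusted p = 0.439 with an estimated correlation).

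Ribosome production and protein folding genes were also higher after acrolein. Of 74 ribosome biogenesis genes 71 rose and 1 fell (72 and 1 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 6.57e-14; adjusted p = 0.439 with an estimated correlation). IMP3 and UTP14, both parts of the small-subunit processing machinery, rose by 2.36 ± 0.19 and 2.34 ± 0.24. Cytosolic ribosomal proteins followed at a smaller size, 79 of 122 up and 2 down, the same adjusted over the list alone, with a median of 0.32 and RPL37A at 1.05 ± 0.11 (camera adjusted p = 5.29e-10; adjusted p = 0.549 with an estimated correlation). All 18 tRNA synthetases rose, 18 adjusted over the list alone, led by MES1 at 1.11 ± 0.10 (camera adjusted p = 1.79e-06; adjusted p = 0.391 with an estimated correlation). Sulfate assimilation and methionine genes gave 20 up and 2 down of 26, the same adjusted over the list alone, with MET16 at 1.64 ± 0.06 and the sulfate permease SUL1 at -1.37 ± 0.33 (camera adjusted p = 4.21e-07; adjusted p = 0.216 with an estimated correlation). MET3, the first enzyme of sulfate assimilation, was lower, at -0.23 ± 0.08 (adjusted p = 0.0202), a call that ended without control replicate 3 (-0.20, adjusted p = 0.0562) and without acrolein replicate 1 (-0.17, adjusted p = 0.0676). Heat shock chaperones gave 16 up and 4 down of 25, the same adjusted over the list alone (camera adjusted p = 0.00645; adjusted p = 0.456 with an estimated correlation). YDJ1, an Hsp40 chaperone, rose by 1.49 ± 0.07, and the small heat shock protein gene HSP26 fell by 0.81 ± 0.05.

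Respiratory, alternative carbon and nitrogen genes fell after acrolein. Of 46 TCA cycle and respiratory chain genes 45 fell and 1 rose, the same adjusted over the list alone, with a median of -0.56 and the citrate synthase CIT3 at -2.79 ± 0.34 (camera adjusted p = 3.9e-11; adjusted p = 0.216 with an estimated correlation). Glyoxylate, gluconeogenesis and fatty acid oxidation genes gave 17 down and 1 up of 20 (18 and 1 adjusted over the list alone), with a median of -1.49 and FBP1, fructose-1,6-bisphosphatase, at -3.25 ± 0.30 (camera adjusted p = 4.92e-05; adjusted p = 0.439 with an estimated correlation). Of 18 nitrogen catabolite genes 16 fell and 1 rose, the same adjusted over the list alone, with a median of -1.62 and DAL80 and MEP2 among the lower ones (camera adjusted p = 3.21e-06; adjusted p = 0.216 with an estimated correlation). In the iron regulon 15 of 25 fell and 5 rose, the same adjusted over the list alone, with the heme oxygenase HMX1 at -3.11 ± 0.16 and FRE5, of the ferric reductase family, at least 16.4-fold lower (camera adjusted p = 0.0136; adjusted p = 0.439 with an estimated correlation). General stress genes under Msn2 and Msn4 gave 27 down and 1 up of 31 (28 and 1 adjusted over the list alone; camera adjusted p = 1.79e-06; adjusted p = 0.391 with an estimated correlation). XBP1 fell by 4.69 ± 0.48 and the catalase gene CTT1 fell by 0.99 ± 0.11. GND2, a 6-phosphogluconate dehydrogenase, was the member that rose, by 2.38 ± 0.14. Reserve carbohydrate genes (trehalose and glycogen) gave 15 down and 2 up of 19 (15 and 3 adjusted over the list alone; camera adjusted p = 0.0136; adjusted p = 0.439 with an estimated correlation). Stationary phase markers gave 8 down and 0 up of 10, the same adjusted over the list alone, with SPG4 at -2.88 ± 0.16 (camera adjusted p = 0.00645; adjusted p = 0.439 with an estimated correlation).

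Cell division genes fell after acrolein. All 9 measured core and variant histone genes were lower, 9 adjusted over the list alone, with a median of -1.11 and HTA1 at -1.28 ± 0.08 (camera adjusted p = 2.2e-05; adjusted p = 0.127 with an estimated correlation). All 13 G2/M genes were lower, 13 adjusted over the list alone, with a median of -1.23, including the mitotic cyclins CLB2 at -2.45 ± 0.19 and CLB1 at -1.77 ± 0.18 (camera adjusted p = 5.64e-05; adjusted p = 0.391 with an estimated correlation). With an estimated correlation, none of the 22 lists called after acrolein stayed called.

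H2O2 changed fewer probe sets than the other treatments. YHK8 was at least 160-fold higher and OYE3 rose by 7.79 ± 0.16 (SE, n = 4 per group, limma adjusted p = 6.1e-13). SRX1, sulfiredoxin, which repairs overoxidised peroxiredoxin, rose by 6.04 ± 0.09 (adjusted p = 1.67e-14), and GPX2, a glutathione peroxidase, by 3.53 ± 0.11. FRM2 was at least 3.12-fold higher. DAK2, a dihydroxyacetone kinase, was at least 21.3-fold higher (adjusted p = 1.23e-09). LSO1, a short protein gene, was at least 2.16-fold higher, by its mean of 6.26 ± 0.73 (SD) after H2O2. Of the probe sets that moved at least 2-fold, 102 were higher and 39 lower. FDH1, formate dehydrogenase, fell by 1.84 ± 0.32 and OSW2 by 1.47 ± 0.10. DAL1, allantoinase, was called lower from a control of 5.73 ± 0.96 (SD), near the background limit, so its bound of 1.5-fold is not firm. PCL1 lay within the background range in both groups, so it has no fold.

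Of 19 Yap1 targets 18 rose after H2O2 and none fell (19 and 0 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 1.23e-33; adjusted p = 0.000781 with an estimated correlation). GSH1 rose by 1.36 ± 0.08, TRR1 by 1.24 ± 0.09, TRX2, thioredoxin, by 0.29 ± 0.03, GRE2, a methylglyoxal reductase, by 2.06 ± 0.09 and YAP1 by 0.86 ± 0.16. In the list of thioredoxin, peroxiredoxin, catalase and superoxide dismutase genes 13 of 19 rose and 0 fell (13 and 3 adjusted over the list alone; camera adjusted p = 8.14e-11; adjusted p = 0.0489 with an estimated correlation). The peroxiredoxin TSA2 rose by 2.26 ± 0.08, the peroxisomal catalase CTA1 by 1.71 ± 0.20 and CCS1, the copper chaperone of superoxide dismutase, by 1.30 ± 0.08. Multidrug transporters gave 9 up and 0 down of 20, the same adjusted over the list alone, with ATR1 at 3.74 ± 0.14 and PDR16 at 1.25 ± 0.12 (camera adjusted p = 6.22e-05; adjusted p = 0.0489 with an estimated correlation). Glutathione and glutaredoxin genes gave 9 up and 3 down of 24 (9 and 4 adjusted over the list alone), with GTT2 at 2.94 ± 0.07 and a list median of 0.01 against a mean of 0.52 (camera adjusted p = 0.000817; adjusted p = 0.251 with an estimated correlation).

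Some iron, amino acid and NADPH genes were higher with H2O2. Of 25 iron regulon genes 13 rose and 1 fell (15 and 1 adjusted over the list alone), with the iron-sulfur scaffold ISU2 at 1.78 ± 0.06 and the ferric reductase FRE1 at 1.21 ± 0.10 (camera adjusted p = 4.49e-09; adjusted p = 0.0712 with an estimated correlation). Amino acid biosynthesis gave 18 up and 4 down of 40, the same adjusted over the list alone, with the homocitrate synthase LYS20 at 2.30 ± 0.13 and ILV5 at -0.81 ± 0.13 (camera adjusted p = 2.19e-05; adjusted p = 0.251 with an estimated correlation). Of 18 pentose phosphate and NADPH genes 5 rose and 0 fell, the same adjusted over the list alone, with GND2 at 2.16 ± 0.14 and GND1 at 0.88 ± 0.04 (camera adjusted p = 0.00287; adjusted p = 0.251 with an estimated correlation). Ribosome biogenesis gave 7 up and 0 down of 74 (6 and 0 adjusted over the list alone), with RPF2 at 1.02 ± 0.24 and a median of 0.34 (camera adjusted p = 3.28e-06; adjusted p = 0.679 with an estimated correlation). It did not pass by fry (adjusted p = 0.174).

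TCA cycle and respiratory chain genes gave 13 down and 3 up of 46 after H2O2 (17 and 4 adjusted over the list alone), and the shift was downward with a median of -0.14 (camera adjusted p = 0.00559; adjusted p = 0.603 with an estimated correlation). It did not pass by fry (adjusted p = 0.399). Its largest member went the other way: CYC1, iso-1-cytochrome c, rose by 2.93 ± 0.05. Nitrogen catabolite genes gave 8 down and 0 up of 18 (11 and 0 adjusted over the list alone), with DAL4, an allantoin permease, at -1.40 ± 0.36 (camera adjusted p = 0.000438; adjusted p = 0.251 with an estimated correlation). The call of DAL4 ended when only the arrays of the control and H2O2 were fitted (adjusted p = 0.0869). Histones gave 5 down and 0 up of 9 (8 and 0 adjusted over the list alone), with HTB2 at -0.44 ± 0.06 (camera adjusted p = 0.000489; adjusted p = 0.0957 with an estimated correlation). G2/M genes gave 8 down and 0 up of 13 (9 and 0 adjusted over the list alone), with SWI5 at -0.54 ± 0.07 (camera adjusted p = 2.57e-05; adjusted p = 0.251 with an estimated correlation). General stress genes went both ways, 3 up and 8 down of 31, the same adjusted over the list alone, with CTT1 at 0.55 ± 0.11 and PAI3 at -1.11 ± 0.18 (camera adjusted p = 0.251; adjusted p = 0.767 with an estimated correlation). HSP26 fell by 0.82 ± 0.05, while SSA4 differed by -0.14 ± 0.06 (adjusted p = 0.105) and HSP12 by -0.15 ± 0.09 (adjusted p = 0.31). With only the arrays of the control and H2O2 in the fit, SSA4 and HSP12 passed (adjusted p = 0.045 and 0.00547). Of the 18 lists called after H2O2, 3 stayed called with an estimated correlation: Yap1 targets, the thioredoxin list and multidrug transporters.

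OYE3 rose after NEM by 8.81 ± 0.16 (SE, n = 4 per group, limma adjusted p = 2.07e-13), FRM2 was at least 165-fold higher, YHK8 at least 179-fold higher, and YOR161C-C, an open reading frame at the floor in the control, at least 30.6-fold higher. ZRT1, the high-affinity zinc transporter, rose by 2.66 ± 0.11 and ZAP1, its transcriptional activator, by 1.73 ± 0.07. Among the decreases, POX1, acyl-CoA oxidase, was at least 70.0-fold lower, FMP45 at least 68.2-fold lower, the transketolase TKL2 at least 16.7-fold lower, and POT1, thiolase, fell by 5.60 ± 0.39.

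All 19 Yap1 targets rose after NEM, 19 adjusted over the list alone, with a median of 1.66, GTT2 at 3.75 ± 0.07 and FLR1 at 3.34 ± 0.07 (camera adjusted p = 2.86e-13; adjusted p = 0.0484 with an estimated correlation). GSH1 rose by 1.82 ± 0.08, TRR1 by 0.93 ± 0.09 and YAP1 by 0.91 ± 0.16. Of 26 sulfate assimilation and methionine genes 24 rose and none fell, the same adjusted over the list alone, with a median of 1.00 (camera adjusted p = 8.8e-15; adjusted p = 0.0484 with an estimated correlation). The sulfate permeases SUL2 and SUL1 rose by 3.02 ± 0.19 and 2.29 ± 0.33. MET8, of siroheme synthesis, rose by 3.22 ± 0.21 and MET3 by 1.75 ± 0.08. Glutathione and glutaredoxin genes gave 14 up and 6 down of 24, the same adjusted over the list alone, with ECM4 at 3.16 ± 0.09 and GPX1 at -2.27 ± 0.14 (camera adjusted p = 0.000482; adjusted p = 0.298 with an estimated correlation). In the thioredoxin list 12 of 19 rose and 6 fell, the same adjusted over the list alone, with SRX1 at 3.12 ± 0.09 and CTT1 at -1.64 ± 0.11 (camera adjusted p = 0.0299; adjusted p = 0.49 with an estimated correlation). That call ended with a replicate block (adjusted p = 0.0557), after quantile normalization (adjusted p = 0.055) and without the dimmest part of the probe sets (adjusted p = 0.0823).

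The zinc regulon split after NEM, 4 of 10 up and 4 down, the same adjusted over the list alone. Besides ZRT1 and ZAP1, ZRT2 rose by 1.39 ± 0.06, and IZH1 fell by 1.57 ± 0.27. As a list it did not pass by camera (median -0.13, mean 0.32, upward, adjusted p = 0.401; adjusted p = 0.509 with an estimated correlation), but it did by fry (adjusted p = 8.19e-10). DNA damage genes gave 8 up and 1 down of 14, the same adjusted over the list alone, with RNR3, a ribonucleotide reductase subunit, at 2.28 ± 0.23 (camera adjusted p = 0.0227; adjusted p = 0.298 with an estimated correlation). The call ended with the dimmest part of the probe sets left out (adjusted p = 0.129). Of 33 proteasome genes 22 rose and 2 fell, the same adjusted over the list alone, with RPT3 at 0.52 ± 0.06 and PRE9 at -0.63 ± 0.05 (camera adjusted p = 0.000482; adjusted p = 0.49 with an estimated correlation). RPN4, the transcription factor of proteasome genes, rose by 0.71 ± 0.04.

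Ribosome biogenesis rose after NEM, 56 of 74 up and 1 down (59 and 1 adjusted over the list alone), with UTP14 at 1.91 ± 0.24 and a median of 0.76 (camera adjusted p = 8.96e-08; adjusted p = 0.552 with an estimated correlation). Cytosolic ribosomal proteins did not pass, with 14 of 122 up and 5 down (4 and 3 adjusted over the list alone), RPL27B at -0.71 ± 0.18 and a median of -0.00 against an upward camera direction (adjusted p = 0.401; adjusted p = 0.909 with an estimated correlation). That list passed upward without NEM replicate 4 (median 0.07, adjusted p = 0.0202).

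Respiratory genes fell after NEM, 45 of 46 down and 0 up (46 and 0 adjusted over the list alone), with a median of -0.47 and the NADH dehydrogenase NDE1 at -1.35 ± 0.06 (camera adjusted p = 5.37e-12; adjusted p = 0.217 with an estimated correlation). Glyoxylate, gluconeogenesis and fatty acid oxidation genes gave 16 down and 1 up of 20, the same adjusted over the list alone, with FBP1 at -2.40 ± 0.30 (camera adjusted p = 0.000192; adjusted p = 0.49 with an estimated correlation). The iron regulon gave 16 down and 6 up of 25, the same adjusted over the list alone, with HMX1 at -2.82 ± 0.16 (camera adjusted p = 0.0148; adjusted p = 0.49 with an estimated correlation). The siderophore transporter SIT1 fell by 2.59 ± 0.08. The list's call ended with the dimmest part of the probe sets left out (adjusted p = 0.0601). Nitrogen catabolite genes gave 15 down and 0 up of 18 (15 and 1 adjusted over the list alone), with the ammonium permease MEP1 at -1.68 ± 0.14 (camera adjusted p = 0.000339; adjusted p = 0.376 with an estimated correlation). General stress genes gave 19 down and 1 up of 31, the same adjusted over the list alone, with ALD3, an aldehyde dehydrogenase, at -1.50 ± 0.17 (camera adjusted p = 0.00119; adjusted p = 0.49 with an estimated correlation). Stationary phase markers gave 8 down and 0 up of 10, the same adjusted over the list alone, with SIP18 at -2.56 ± 0.30 (camera adjusted p = 0.00908; adjusted p = 0.49 with an estimated correlation). HSP12 fell by 0.97 ± 0.09, SSA4 by 0.52 ± 0.06 and HSP26 by 0.23 ± 0.05.

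All 9 histone genes were lower after NEM, 9 adjusted over the list alone, with HTB2 at -0.95 ± 0.06 (camera adjusted p = 0.000209; adjusted p = 0.118 with an estimated correlation). G2/M genes gave 2 up and 3 down of 13, the same adjusted over the list alone, with CLB1 at -1.05 ± 0.18 and BUD4 at 0.65 ± 0.10 (camera adjusted p = 0.876; adjusted p = 0.947 with an estimated correlation). The median was -0.11, and the direction by camera turned upward without control replicate 4 (median -0.08), NEM replicate 1 (median -0.04) or NEM replicate 3 (median -0.08). Of the 19 lists called after NEM, 2 stayed called with an estimated correlation, Yap1 targets and sulfate assimilation.

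**Figure D3:**
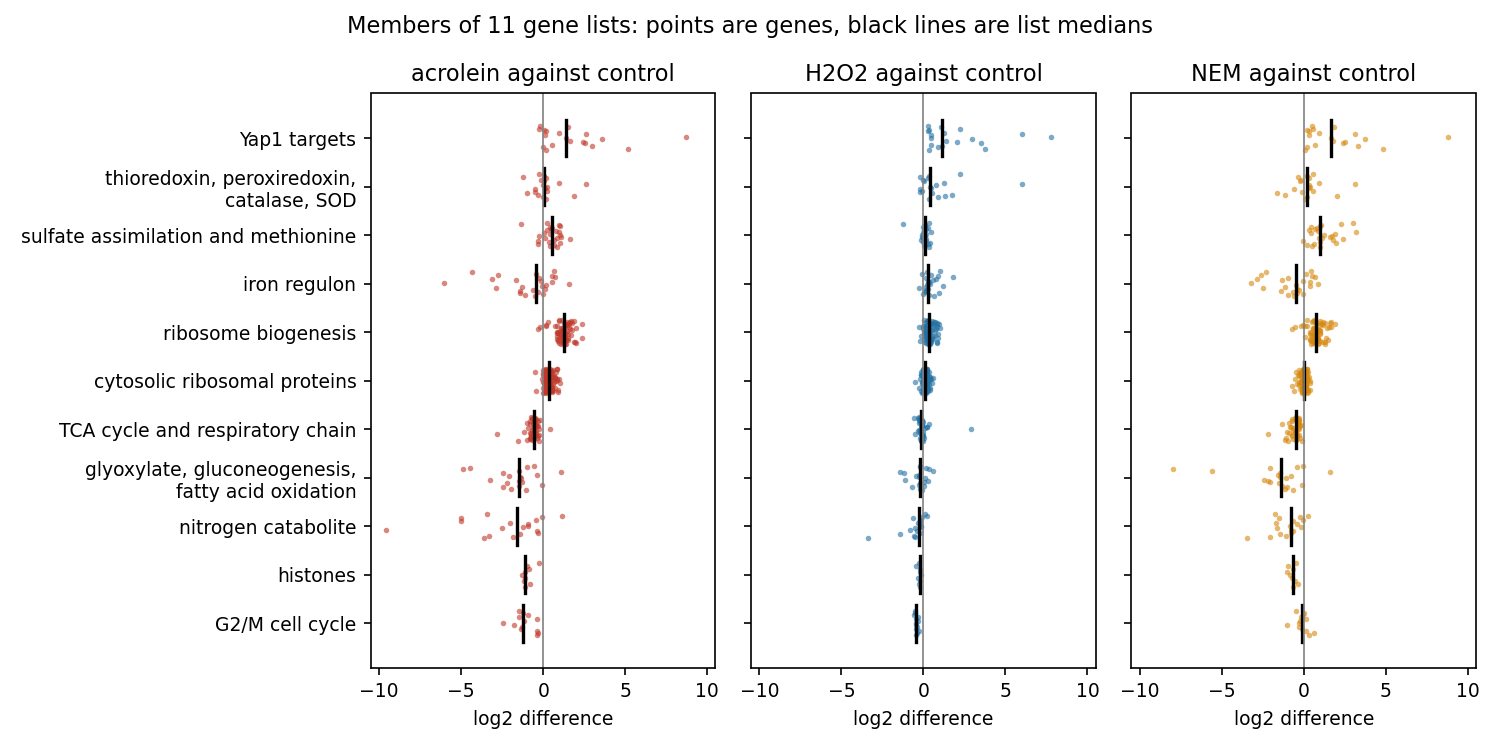
Log2 difference from the control for each measured member of 11 gene lists after acrolein, H2O2 and NEM, with 1 point per gene and a black line at the list median. Yap1 targets lie to the right in all 3 panels, with medians of 1.39, 1.16 and 1.66, while respiratory genes lie to the left after acrolein (-0.56) and NEM (-0.47).

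Acrolein and NEM, both thiol-reactive alpha,beta-unsaturated carbonyl compounds, were given at different doses (0.05 and 0.016 mM), so their values stand side by side. Among the oxidant-defence and other response genes named here, some did not differ detectably between them and some did. SRX1 and TRX2, for example, were lower with acrolein, at -0.52 ± 0.09 and -0.19 ± 0.03 (limma adjusted p = 0.000465 and 0.000689). OYE3 read 15.47 ± 0.15 with acrolein and 15.60 ± 0.06 with NEM (SD), near the highest value of the file (16.28), where differences may be harder to see. The acrolein minus NEM difference was -0.13 for OYE3 (95% interval -0.49 to 0.22, limma adjusted p = 0.527), -0.09 for GRE2 (-0.30 to 0.11, adjusted p = 0.441), and 0.13 for GPX2 (-0.11 to 0.37, adjusted p = 0.36). It was 0.03 for TRR1 (-0.15 to 0.22, adjusted p = 0.798), changing to -0.01 without NEM replicate 1, and 0.01 for RPN4 (-0.07 to 0.10, adjusted p = 0.814), changing to -0.01 without acrolein replicate 2 and to -0.00 without acrolein replicate 4. HSP12 did not pass (0.22, 0.02 to 0.43, adjusted p = 0.0645). It passed without NEM replicate 3 (0.31, adjusted p = 0.00973), NEM replicate 2 (0.27, adjusted p = 0.0471) or acrolein replicate 1 (0.27, adjusted p = 0.045). It also passed with a replicate block (adjusted p = 0.0443), with a trended and robust variance prior (adjusted p = 0.0462) and without the dimmest part of the probe sets (adjusted p = 0.0493). YAP1 was lower with acrolein than with NEM, by -0.83 ± 0.16 (adjusted p = 0.000836).

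In all, 2884 probe sets differed between acrolein and NEM, 1393 higher with acrolein and 1491 lower, 237 of them at least 2-fold. DAL80 was at least 65.0-fold lower with acrolein and YHP1, a cell cycle repressor, at least 20.3-fold lower, while FMP45 was at least 31.0-fold higher and the kinase gene FMP48 4.94 ± 0.21 higher. Sulfate assimilation genes were lower with acrolein, 20 of 26 lower and 1 higher, the same adjusted over the list alone, with SUL1 at -3.67 ± 0.33 and MET3 at -1.98 ± 0.08 (camera adjusted p = 3.52e-08; adjusted p = 0.374 with an estimated correlation). All 13 G2/M genes were lower, 13 adjusted over the list alone, with CLB2 at -2.16 ± 0.19 (camera adjusted p = 1e-07; adjusted p = 0.374 with an estimated correlation). Of 33 proteasome genes 27 were lower and 1 higher, the same adjusted over the list alone, with PUP1 at -0.84 ± 0.09 (camera adjusted p = 1.18e-06; adjusted p = 0.405 with an estimated correlation). Of 122 cytosolic ribosomal protein genes 88 were higher and 0 lower (93 and 0 adjusted over the list alone), with RPS0B at 0.81 ± 0.15 (camera adjusted p = 1.06e-11; adjusted p = 0.6 with an estimated correlation). Yap1 targets were 11 lower and 0 higher of 19, the same adjusted over the list alone, with TSA2 at -0.79 ± 0.08 (camera adjusted p = 0.00607; adjusted p = 0.476 with an estimated correlation). Nitrogen catabolite genes were 10 lower and 4 higher of 18 (11 and 4 adjusted over the list alone; camera adjusted p = 0.013; adjusted p = 0.6 with an estimated correlation). That call ended without the dimmest part of the probe sets (adjusted p = 0.069). None of the 15 lists called here stayed called with an estimated correlation.

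Acrolein and NEM were also compared with H2O2. SRX1 was -3.44 ± 0.09 with acrolein relative to H2O2 and -2.92 ± 0.09 with NEM (limma adjusted p = 1.72e-11 and 5.7e-11), and DAK2 was at least 21.3-fold lower with each. CYC1 was -2.54 ± 0.05 with acrolein and -3.20 ± 0.05 with NEM. In the iron regulon 20 of 25 genes were lower and 2 higher with acrolein than with H2O2, the same adjusted over the list alone, with TIS11, which promotes decay of certain transcripts when iron is short, at -4.62 ± 0.15 (camera adjusted p = 1.58e-08; adjusted p = 0.214 with an estimated correlation). NEM gave 21 lower and 1 higher, the same adjusted over the list alone, with HMX1 at -3.61 ± 0.16 (camera adjusted p = 5.63e-09; adjusted p = 0.184 with an estimated correlation). The thioredoxin list was 16 lower and 2 higher of 19 with acrolein, the same adjusted over the list alone, with TSA2 at -2.49 ± 0.08 (camera adjusted p = 8.75e-05; adjusted p = 0.287 with an estimated correlation).

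Ribosome biogenesis was higher with acrolein than with H2O2, 67 of 74 genes higher and 1 lower (68 and 1 adjusted over the list alone), with IMP3 at 1.49 ± 0.19 (camera adjusted p = 1.18e-10; adjusted p = 0.443 with an estimated correlation). Sulfate genes were higher with NEM than with H2O2, 23 of 26 and 0 lower, the same adjusted over the list alone, with MET16 at 2.25 ± 0.06 (camera adjusted p = 3.82e-15; adjusted p = 0.0888 with an estimated correlation). TCA cycle and respiratory chain genes were lower with acrolein than with H2O2 for 43 of 46 members and higher for 0, the same adjusted over the list alone (camera adjusted p = 3.05e-12; adjusted p = 0.249 with an estimated correlation). With NEM 35 were lower and 0 higher (37 and 0 adjusted over the list alone; camera adjusted p = 5.59e-10; adjusted p = 0.322 with an estimated correlation). Pentose phosphate and NADPH genes were lower with NEM, 12 of 18 against 1 higher, the same adjusted over the list alone, with GND2 at -2.22 ± 0.14 (camera adjusted p = 0.00256; adjusted p = 0.322 with an estimated correlation). In all, 3232 probe sets differed between acrolein and H2O2 (1500 higher, 1732 lower) and 3026 between NEM and H2O2 (1452 higher, 1574 lower).

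**Figure D4:**
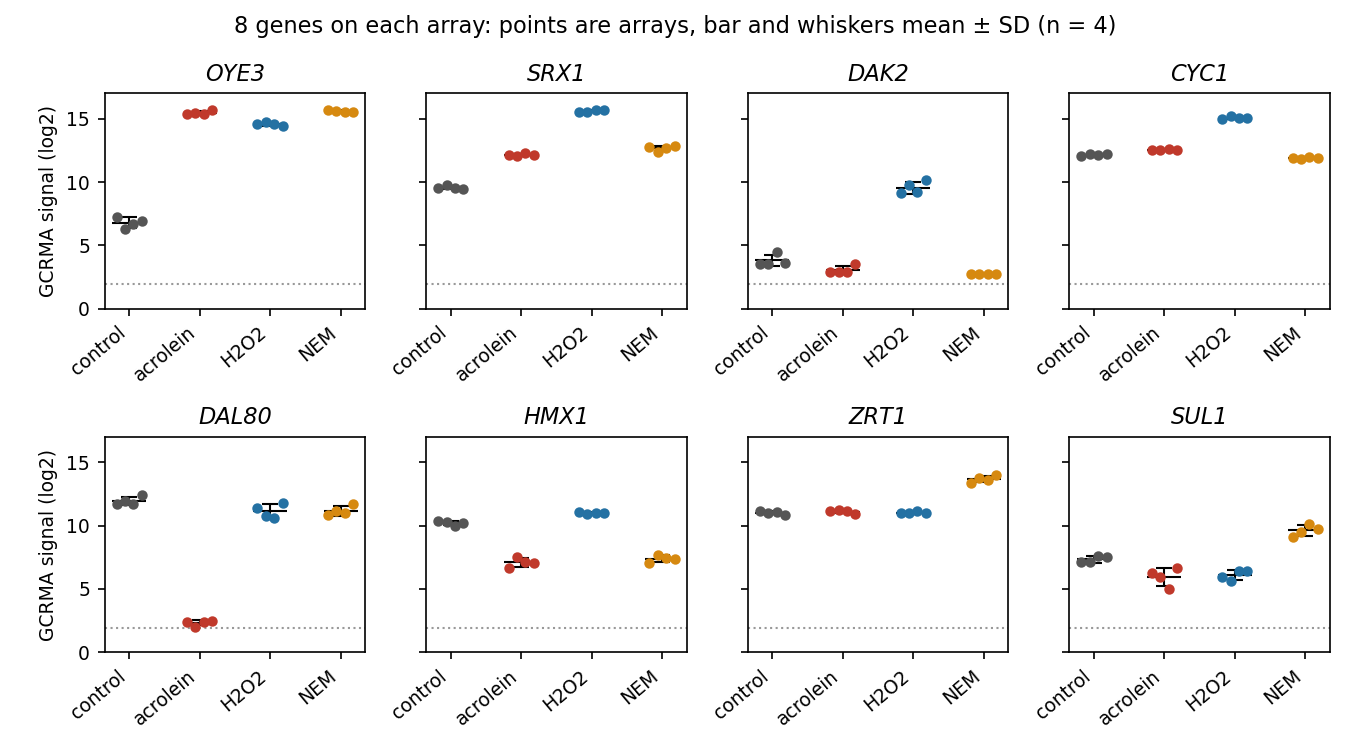
GCRMA signal on the log2 scale for 8 genes in the 4 groups, with 1 point per array, a bar at the mean and whiskers of 1 SD (n = 4), and a dotted line at the lowest value of the file. OYE3 is above the control after all 3 treatments, DAK2 and CYC1 after H2O2, and SUL1 and ZRT1 after NEM. DAL80 stands near the floor after acrolein alone.

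Some genes were called against the control and against both other treatments in the same direction. They numbered 1243 for acrolein (545 higher, 698 lower), 1133 for NEM (518 higher, 615 lower) and 225 for H2O2 (111 higher, 114 lower). For acrolein they included PET18, a thiaminase-like gene, at 4.24 ± 0.20 above the control and 4.69 ± 0.20 above NEM, TPO1, a polyamine transporter, at 2.79 ± 0.13 above the control, and DAL80 and MEP2 among the lower genes. For H2O2 they included SRX1, DAK2 and CYC1 on the higher side and MND1, a meiotic gene, on the lower side, at -0.98 ± 0.14. For NEM they included MET5, of sulfite reduction, at 1.94 ± 0.06, MET3, ZRT1 and ZAP1 on the higher side and MDM35, a mitochondrial intermembrane protein gene, on the lower side, at -2.29 ± 0.09. Genes in these counts could respond to the other treatments too. SRX1 stood above the control by 2.59 with acrolein and 3.12 with NEM, and TPO1 by 0.42 with H2O2 and 0.87 with NEM.

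Many of the same genes changed in the same direction under different treatments. Acrolein and NEM shared 2435 probe sets, 1019 higher and 1416 lower, and 136 were called in opposite directions. Acrolein and H2O2 shared 863 (417 higher, 446 lower, 80 opposite), and H2O2 and NEM 741 (364 higher, 377 lower, 141 opposite). All 3 raised 340 probe sets, OYE3, GRE2 and GSH1 among them, and lowered 342. Unchanged groups, simulated with 4 simulated control arrays in common, shared 0.01 probe sets on average over 100 simulations. Almost nothing is called where nothing changes, so a count near 0.01 was due there. Independent lists of these sizes would share 414.9 higher and 686.6 lower for acrolein and NEM, 145.1 and 226.3 for acrolein and H2O2, and 141 and 197.7 for H2O2 and NEM. With the controls split into 2 pairs of arrays, 1837 to 2076, 411 to 626 and 379 to 507 probe sets were shared. Neither reference holds both the effects and the shared controls, so the excess over either is not an estimate of a common response.

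Across the 5785 probe sets, which are not independent replicates, the log2 differences correlated at Pearson r = 0.79 for acrolein and NEM, 0.61 for acrolein and H2O2 and 0.53 for H2O2 and NEM. Unchanged groups sharing the controls gave 0.50 on average in simulation for each pair. The covariances were 0.54, 0.22 and 0.18, against 0.01 simulated for each. With the controls split, the correlations were 0.74 to 0.80, 0.53 to 0.61 and 0.48 to 0.50.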

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

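The count of other splits and the test without acrolein replicate 1 were set before their results were seen; the covariate of 7 ribosomal RNA probe sets replaced one of 4 chosen probe sets after that result was seen.

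The check covered 472 groups of 4 arrays, for 116 named genes and 4 measures per array. In 33 (6.99%) 1 array lay apart from the other 3, where chance gives about 1 in 20 for normally spread values. The gap of that array to its nearest neighbour, as a share of the range of the group, exceeded 0.829 in each. Tied values give a share of 1.000 for any gap, as for LEU2 in H2O2 (1.9781 against 1.9218). The 6.99% is therefore not a measured excess over 1 in 20. In the control it was 0.904 for DAK2 and 0.832 for YKL070W (replicate 3 highest), 0.944 for MDM35 and 0.922 for SRX1 (replicate 2 highest), 0.929 for RPN4 (replicate 1 highest), 0.895 for SUL2 (replicate 3 lowest), 0.860 for TIS11 (replicate 2 lowest) and 0.946 for TRX2 (replicate 1 lowest). In acrolein it was 0.975 for DAK2 (replicate 4 highest), 1.000 for DAL1 (replicate 3 highest), 0.887 for DAL80 (replicate 2 lowest), 0.832 for MET5 (replicate 3 lowest), 0.844 for TAH18 (replicate 1 highest) and 0.879 for ZRT1 (replicate 4 lowest). In H2O2 it was 0.937 for CCS1 and 0.834 for PDR16 (replicate 4 lowest), 0.898 for GCV2 (replicate 4 highest), 0.905 for FLR1 (replicate 1 lowest), 1.000 for DAL1 and LEU2 (replicate 1 highest), and 0.865 for SWI5 and 0.864 for ZAP1 (replicate 3 lowest). In NEM it was 1.000 for DAL1 and 0.847 for TRX2 (replicate 3 lowest), 0.886 for POX1 (replicate 3 highest), 0.883 for FRE5 (replicate 1 lowest), 0.933 for GPX2 (replicate 1 highest), 0.999 for LSO1 and 0.959 for PAI3 (replicate 2 highest), and 0.839 for TKL2 (replicate 4 lowest). Among the measures per array it was 0.955 for the 3′ minus 5′ signal of control replicate 2, the highest, 1.000 for the number of other-species probe sets above the floor in control replicate 4, the highest, and 0.875 for the median of H2O2 replicate 3, the lowest.

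Probe sets outside the comparisons gave signal above the control arrays. The mean over 7 ribosomal RNA probe sets, at most 11.5547 in the control, was 15.4836, 11.7725 and 12.5184 in acrolein replicates 1, 2 and 3, 11.5552 in H2O2 replicate 2, and 12.3537, 11.9382 and 12.6366 in NEM replicates 1, 2 and 3. Of 1747 probe sets of another yeast species at most 11 were above the floor in the control, against 17, 22 and 14 in acrolein replicates 1, 2 and 3. In H2O2 there were 14, 14 and 12 in replicates 1, 2 and 4, and in NEM 22, 13, 26 and 53 in replicates 1 to 4.

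Acrolein replicate 1 combined the highest ribosomal RNA mean, 15.48, with the highest 3′ minus 5′ signal, 1.20. If this array made most of the acrolein calls, most would go without it, but the number called without it, divided by the number with it, was 0.9487, which argues against that. With the ribosomal RNA signal of each array as a covariate, a share of 0.9625 of the called probe sets stayed called in the same direction, which argues against that signal as the main driver there. The share was 0.926 for H2O2, 0.9923 for NEM, 0.7698 for acrolein and H2O2 (2742 called, against 3232), 0.9882 for acrolein and NEM and 0.9068 for NEM and H2O2. Acrolein itself and the preparation of that RNA both stay open, untested, as the source of the high signal.

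H2O2 replicate 4 had the lowest ribosomal RNA mean, 4.38, further below the control range than acrolein replicate 1 lay above it. Without H2O2 replicate 4, 911 probe sets were called after H2O2, and a share of 0.7474 of the 1148 stayed called in the same direction. Leaving out any other single array of these groups gave 877 to 1107. The source of the low signal was not tested.

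With all 35 splits of the 8 arrays taken as alike, a share under 0.05, only the real split, called as many probe sets in each comparison. The other splits leave the treatment difference inside the groups, which widens the spread, so few calls were due in them. Since the arrays of a group may not be separate cultures, chance between cultures is not excluded. The real value and the highest of the other splits were 3704 and 4 for acrolein, 1148 and 1 for H2O2, and 3390 and 0 for NEM against the control. Between treatments they were 3232 and 4 for acrolein and H2O2, 2884 and 5 for acrolein and NEM, and 3026 and 0 for NEM and H2O2. Where the numbers pair the arrays (acrolein and control, NEM and control, acrolein and NEM), only 8 splits part all 4 pairs, too few for a share under 0.05. The real one gave the values above and the others 0 each, and the other splits with calls left some pairs together.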

How the results depend on the processing

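The alternatives without acrolein replicate 1 and NEM replicate 4 together, with a ribosomal RNA covariate and with named genes alone were chosen after seeing the data. For 22 results on whole comparisons, 428 of 452 values stayed near the reported one and 24 moved. Near is a wide tolerance here, since counts of 877 and 1555 for H2O2 both counted as near 1148. Correlations were judged against their SD between replicate arrays. For the 69 list results, 961 of 1034 values kept direction and call, 66 lost the call, 4 gained it and 3 turned. For 471 gene results it was 10085 of 10188, 53, 44 and 6. Counted by result, only 6 of the 22 on whole comparisons, 7 of the 69 on lists and 442 of the 471 on genes held in every setting. No called probe set was called in the opposite direction in any alternative fit (0 in each). With each array left out in turn the counts were 3454 to 3629 for acrolein, 877 to 1107 for H2O2, 3163 to 3264 for NEM, 2856 to 3148 for acrolein and H2O2, 2396 to 2880 for acrolein and NEM and 2789 to 2914 for NEM and H2O2. With a replicate block they were 3928, 1475, 3653, 3543, 3226 and 3335; same-numbered H2O2 arrays correlated at -0.22 to 0.69 with the control, -0.38 to 0.42 with acrolein and -0.19 to 0.59 with NEM. H2O2 replicates 3 and 4 correlated best with their own number in each group (0.37 to 0.69), replicate 1 with number 2 (0.44 to 0.50) and replicate 2 with number 1 (0.39 to 0.53). Numbers 1 and 2 of H2O2 may thus have been exchanged, which stays undecided, and the block by the given numbers is not apt for H2O2. Without acrolein replicate 1 and NEM replicate 4 they were 3569, 1297, 3358, 3066, 2241 and 2992. Calls of at least 2-fold numbered 763, 141, 650, 461, 237 and 497, fewer by construction, as were the 601 for H2O2 at adjusted p under 0.01. Lists called with an estimated correlation in camera were 0, 3, 2, 0, 0 and 0, in the same order, and by fry 35 for acrolein, 17 for H2O2, 34 for NEM, 34 for acrolein and H2O2, 31 for acrolein and NEM and 29 for NEM and H2O2; fry asks whether a list moves at all. Correlations by Spearman were 0.7372 for acrolein and NEM and 0.4416 for H2O2 and NEM. For H2O2 and NEM the correlation was 0.5804 without the dimmest probe sets and 0.491 with split controls, where shared calls fell to 438.3, and to 508.5 for acrolein and H2O2, with fewer control arrays. ACT1 after H2O2 turned to -0.003 with the ribosomal RNA covariate and ran from -0.0064 to 0.0617 with 1 array left out. With 1 array left out, YAP1 after acrolein ran from -0.036 to 0.2345, the acrolein minus NEM difference from -0.0059 to 0.0408 for RPN4 (-0.0025 without acrolein replicate 4) and from -0.0123 to 0.0888 for TRR1. The G2/M list median after NEM ran from -0.1857 to -0.0382, and its direction by camera turned without control replicate 4 (-0.0777), NEM replicate 1 or NEM replicate 3 (-0.0771). Except where the construction shows it, the cause was not tested. A log2(value + 16) transform was not run since the values are log2 already, and a fit of the 2 groups compared alone cannot give the result for any treatment. Low signal limits folds: 94 tested genes stood at the floor on some arrays.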

Other observations

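The tests of an earlier growth stage, of divergent neighbours and of tandem pairs among those not divergent, and the choice of MAK31 and MAK32, came only after their results were seen.

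Further gene lists moved after acrolein or NEM. Of 66 mitochondrial ribosomal protein genes 43 fell after acrolein and 5 rose (43 and 6 adjusted over the list alone), with MRP17 at -0.93 ± 0.08 (camera adjusted p = 0.000504; adjusted p = 0.439 with an estimated correlation). After NEM 35 fell and 6 rose, the same adjusted over the list alone, with MRP17 at -1.58 ± 0.08 (camera adjusted p = 0.00379; adjusted p = 0.497 with an estimated correlation). Of 19 genes of RNA polymerases I and III 12 rose after acrolein and 2 fell, the same adjusted over the list alone, with RPA49 at 2.06 ± 0.30 (camera adjusted p = 0.00628; adjusted p = 0.58 with an estimated correlation). Purine and one-carbon genes gave 11 up and 1 down of 17 after acrolein, the same adjusted over the list alone, with SHM2, serine hydroxymethyltransferase, at 0.99 ± 0.09 (camera adjusted p = 0.00516; adjusted p = 0.439 with an estimated correlation). After NEM they gave 11 up and 0 down, the same adjusted over the list alone, with GCV2, of glycine cleavage, at 1.23 ± 0.12 (camera adjusted p = 0.00614; adjusted p = 0.49 with an estimated correlation). Of 15 M/G1 genes 12 fell after acrolein and 0 rose, the same adjusted over the list alone, with DSE4, a daughter-cell glucanase, at -1.61 ± 0.16 (camera adjusted p = 0.00355; adjusted p = 0.439 with an estimated correlation).

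PET18, MAK31 and HTL1 follow each other on the reference genome, and MAK32 lies nearby. PET18 rose by 4.24 ± 0.20 after acrolein (limma adjusted p = 8.1e-10), HTL1, of a chromatin remodelling complex, by 1.97 ± 0.16 (adjusted p = 2.41e-07), MAK31 by 1.35 ± 0.14 (adjusted p = 1.89e-06) and MAK32 by 0.98 ± 0.03 (adjusted p = 2.19e-11). All 4 were higher with acrolein than with NEM, by 4.69 ± 0.20, 2.38 ± 0.16, 1.66 ± 0.14 and 0.37 ± 0.03. No explanation for the shared rise was tested.

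Respiratory, glyoxylate and general stress lists were lower and ribosome biogenesis was higher after both acrolein and NEM. None of these list calls stayed with an estimated correlation. Array scaling was predicted to lose the falls under quantile normalization, but the smallest fall of the 6 list medians was then 0.3061. Array medians ran only from 11.85 to 11.92 before that step. It could therefore move the lists little whatever the cause, so the result cannot decide on scaling, which stays open. An earlier growth stage of the treated cultures stays open. Of 7 growth-linked lists 7 moved the way of a younger culture after acrolein and 5 after NEM, but 4 of the 7 are the pattern itself. Of the 3 others (cytosolic ribosomal proteins, stationary phase markers and reserve carbohydrate genes), 3 moved that way after acrolein and 1 after NEM, 0 with an estimated correlation. After NEM the reserve carbohydrate genes (trehalose and glycogen) gave 4 up and 8 down of 19, the same adjusted over the list alone (camera adjusted p = 0.838; adjusted p = 0.909 with an estimated correlation). By a first criterion, fewer than 6 of 7, the NEM result argued against an earlier stage. That criterion was loosened after the result was seen, so that only a list moving the other way counts against it, and the 4 lists of the pattern were taken out later still. The treatments themselves stay open and untested as the source, and culture density was not analysed here.

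Genes raised at least 2-fold after NEM often lay side by side. Of 249 such genes 16.9% had a raised neighbour, against a median of 8.03% in 10000 random gene sets, and a share of 0.9993 of the random sets had less. Transcription running on into the next gene on the same strand would favour tandem pairs, and 8 of the 21 raised pairs were tandem. That is 38.1% (exact 95% interval 18.1 to 61.6), against 47.8% of all adjacent pairs (one-sided exact binomial p = 0.867). By the criterion set in advance, a share at or below that of all pairs counts against running on, but the interval takes in 47.8%. Among the 9 raised pairs that were not divergent (transcribed away from each other) the 8 tandem ones made up 88.9%. Of all such pairs 64.3% were tandem (one-sided exact binomial p = 0.112). That later subset leans the other way, and its pairs are too few to decide. Divergent pairs made up 12 of the 21 (57.1% against 25.6%, one-sided exact binomial p = 0.00211), YLR460C and PAU4, CYT2 and SRX1, and ARR2 and ARR3 among them, so control regions shared by both genes may be an explanation. That reading was found and tested on the same data, and NEM acting on each gene apart stays open. The binomial tests take the pairs as independent, which was not checked. YCR102C with PAU3 and YLR460C with PAU4 both count, and related genes may not be independent.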
